A study of Homo sapiens with 6 samples.

How the data were processed

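PRO-seq libraries of SBC-3 cells given a control siRNA or either of 2 siRNAs against SFPQ, with 2 libraries per group, were analysed from the deposited processed values. Per the submitters' processing notes, the tools were UMI-tools, cutadapt 1.14, Bowtie2, SAMtools 1.3.1 and DESeq2 1.38.1, and the genome builds hg38 and dm6. Neither the order of these steps nor the role of the fly build is given in the sources used here, and the same holds for the annotation, the part of each gene that was counted and the use of strand. Median-of-ratios scaling over the tested human features left the counts of genes called higher and lower in the deposited normalized reads as they were (5400 and 5044). Whether fly reads entered the scaling of the deposited profiles is not given in the sources used here. A change of total transcription in all genes could not be seen in the normalized reads.

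The authors' deposited table gave signal per feature as normalized reads, with 1 value per library. Every value in a library was a whole multiple of the value of 1 read (100% of values at a tolerance of 0.1 read), so whole reads were recovered: 18475158 and 12072813 for siCtrl, 15425585 and 12990457 for siSFPQ-2, and 13323238 and 15029609 for siSFPQ-3. Depth limits genes of few reads most, since the value of 1 read lay between 0.797 and 1.11. The 2 largest features took 15.2, 10.9, 7.36, 10.3, 7.79 and 13.9% of the deposited normalized totals in the same order. The ratio of the mean siSFPQ total to the mean siCtrl total was 1.03. The authors' deposited table also held a log2 fold change of siSFPQ over siCtrl and an adjusted p-value, empty for 2006 features, which were only set beside the values computed here. For each library the authors deposited signal in 500 bins along each gene, in classes named up, ns and down. The scaling of these profiles and the bin sizes are not given in the sources used here. The first and last 100 bins were assumed to lie on either side of a gene scaled to the 300 bins between them, and no value computed here uses a size of the outer bins.

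Of 26067 lines of the table, 240 repeats were removed, leaving 25827 features, of which 191 had no Ensembl gene identifier and 19 symbols named 2 features each. Spans and coordinates came from a RefSeq gene table of the GRCh38.p14 assembly, the same build as hg38. It matched 18746 features by symbol, 401 by synonym and 40 by accession, and 6640 had no match. Features with a value of at least 10 in at least 2 libraries were tested, which left 21773.

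Lists of the siRNA difference were also tested without each library, a step added after seeing the data. The choices of groups, tests, gene lists and alternatives were made before the data were examined, except where stated. The ratios between windows, and the split at 300 kb of genes over 100 kb, were not among these planned choices. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with the trend option, in a single fit of 3 groups. The contrasts were the mean of the siSFPQ groups against siCtrl, each siRNA against siCtrl, and siSFPQ-3 against siSFPQ-2. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 10.7 for siCtrl, 11.4 for siSFPQ-2 and 23.6 for siSFPQ-3, so no pair was taken to be the same library, which does not show that they were biological replicates. The labels give no batches, groups of 2 are too small for a test of single libraries as outliers, and other splits of the samples were not counted for the same reason. The labels' replicate numbers were not used as a pairing.

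Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and adjusted over 35 lists. These were lists of signalling, stress, metabolic, transcription and RNA processing genes, hosts and genes of microRNAs, and cell type markers. The list of endothelial genes had 4 tested members of 13 and was left out. Lists share some members, among them CCND1 and MYC. The named genes were SFPQ, NONO, PSPC1 and NEAT1, then the 10 largest rises and 10 largest falls that passed the threshold. These had the same sign with each siRNA, the 4 siSFPQ libraries on one side of both siCtrl libraries, a mean of at least the median of tested genes (287 normalized reads) and a symbol that is no clone name. From each list came up to 2 members past the threshold in each direction with the smallest p, or the member with the smallest p where none passed, from the microRNA hosts and genes up to 5, and between the siRNAs the 5 largest in each direction, which gave 166 genes, of which 2 are not reported here.

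The expected correlation of fold changes that share controls came from 20 simulations of unchanged groups. For profiles, the promoter window was planned as the first 150 bases of the gene and the downstream window from 250 bases to the last bin. Since gene bins are scaled, these windows were placed at the median span of tested genes, 24531 bases or 81.8 bases per bin, and so took bins 101 to 102 and bins 104 to 500. In shorter and longer genes they cover fewer and more bases. Genes listed in more than 1 class, 17 in number, were left out of the profiles. The window fit took log2(window sum + 1) of 20515 genes. Ratios between windows used 12549 genes with a mean body signal of at least 2 and added 0.5 to each window's mean signal.

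Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 50, TMM, median-of-ratios and same-total scalings, robust empirical Bayes, a 2-group fit, a replicate block, a fold of at least 1.5, each library left out in turn, fry, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. For profiles they were a promoter window of 300 bases, medians over genes, genes scaled to their own total and libraries scaled to the same total. Chosen after seeing the data were windows with signal in at least 3 libraries, the gene body bins alone, edgeR and DESeq2 for the authors' classes, and the totals without the 2 largest features. Tables were handled with the data.table package (1.17.8) and pandas 2.3.3 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.

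The steps were tested on simulated data for both siRNAs against siCtrl over 21690 genes. limma recovered 80 of 97 genes changed by 1 on the log2 scale and 97 of 97 changed by 2, with 5 false calls (2.75% of calls). edgeR recovered 81 and 97 with 6 false calls. At the preset correlation an unchanged list had a camera p = 0.980, and Spearman's rho with span was 0.0120 without and 0.365 with a planted trend. Genes were simulated independently of one another, so this cannot show how the preset correlation acts on lists of correlated genes. Camera with an estimated correlation was not tried on the simulated data.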

Results

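Nascent transcription was measured by PRO-seq, which sequences RNA extended by engaged RNA polymerases in permeabilized cells, in SBC-3, a human small cell lung cancer line. Cells received a control siRNA (siCtrl) or either of 2 siRNAs against SFPQ (siSFPQ-2 and siSFPQ-3) at 10 nM and were harvested after 72 h, with n = 2 libraries per group. SFPQ encodes an RNA- and DNA-binding protein of paraspeckles, nuclear bodies built on the long non-coding RNA NEAT1. The comparisons address how depletion of SFPQ alters nascent transcription, that of primary microRNA transcripts included. The libraries held between 12072813 and 18475158 reads over 25827 annotated features, of which 21773 passed the filter and were tested. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Values are the deposited normalized reads, and fold changes are on the log2(value + 1) scale, which understates the change of low genes.

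SFPQ itself, on chromosome 1 from 35176380 to 35193145 (hg38), had normalized read counts of 2295 and 2435 in the siCtrl libraries, 1825 and 1972 with siSFPQ-2, and 1922 and 2466 with siSFPQ-3. The mean was 2365 ± 99.3 (SD, n = 2) in siCtrl and 2046 ± 286 (SD, n = 4) with both siRNAs, a log2 fold change of -0.22 (SE 0.11) that did not pass the threshold (limma, adjusted p = 0.137). The siRNAs taken singly gave log2 fold changes of -0.32 (adjusted p = 0.0778) and -0.12 (adjusted p = 0.491). An siRNA acts on mature mRNA, so nascent reads of the target do not measure the knockdown, and the labels could not be checked this way. The SFPQ partner NONO, on the X chromosome, had a log2 fold change of -0.06 (adjusted p = 0.602), and the third family member PSPC1 one of 0.21 (adjusted p = 0.104); neither passed. NEAT1 (chromosome 11, 65422798 to 65445540) rose from 1947 ± 102 (SD, n = 2) to 3089 ± 309 (SD, n = 4), a log2 fold change of 0.66 (SE 0.11, adjusted p = 8.41e-04), with the 4 siSFPQ libraries above both siCtrl libraries. Omitting the second siSFPQ-3 library brought SFPQ past the threshold, at -0.31 (adjusted p = 0.0255).

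With both siRNAs against siCtrl, TNFRSF9, the costimulatory receptor CD137 (chromosome 1, 7915871 to 7940839), rose from 48.5 ± 6.60 (SD, n = 2) to 1212 ± 410 (SD, n = 4) normalized reads, a log2 fold change of 4.56 (SE 0.25, adjusted p = 4.77e-07) or 23.6-fold. The OX40 ligand gene TNFSF4 rose from 28.7 ± 3.34 to 473 ± 28.2, and the neuronal adhesion gene CNTNAP2 (chromosome 7, 146116801 to 148420998) rose from 258 ± 10.6 to 3984 ± 454, a log2 fold change of 3.94. In the other direction, KBTBD11 (chromosome 8, 1973677 to 2006936) fell from 783 ± 63.3 to 131 ± 42.3, a log2 fold change of -2.63 (SE 0.20, adjusted p = 4.20e-06), and NAALADL2 fell from 2508 ± 412 to 429 ± 159, a log2 fold change of -2.61. The interferon-induced IFIT1 (log2 fold change -2.37) and GINS4, a subunit of the replicative helicase complex (log2 fold change -2.18), followed.

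Further genes among the 10 with the largest rise that met the rule for named genes were the receptor phosphatase PTPRB (log2 fold change 3.92), the transmembrane collagen COL13A1 (3.90), ANO3 (3.87), the collagen receptor subunit ITGA2 (3.75), and the transcription factors CREB5 (3.73) and RUNX2 (3.72), with the inflammatory caspase CASP4, which rose from 50.2 ± 6.77 to 711 ± 64.9. Among the 10 with the largest fall under the same rule were the lysophospholipase D gene ENPP2 (log2 fold change -2.11), the mitochondrial import gene TIMM21 (-2.11), the glutamate receptor gene GRIK1 (-2.02), TP63 (-1.94) and the mitotic kinase gene PBK (-1.93). For each of these genes the 4 siSFPQ libraries lay on one side of both siCtrl libraries. Across the 21773 tested genes, 5400 were higher and 5044 lower at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 3624 and 2879 of them by at least 1.5-fold. Protein-coding genes numbered 3985 higher and 3223 lower of 14020, long non-coding RNAs 1018 higher and 1367 lower of 5114, and snRNA genes 4 higher and 29 lower of 107. The share of normalized reads on nuclear copies of mitochondrial genes was higher in the 4 siSFPQ libraries than in both siCtrl libraries, at 1.34 and 0.907% in siCtrl, 1.79 and 1.44% with siSFPQ-2 and 1.80 and 1.51% with siSFPQ-3. Each siCtrl library carried much weight: without the first, 3961 genes were higher and 2463 lower, and without the second, 3622 and 2529.

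Genes of cell proliferation fell together. Of 45 tested E2F and S phase genes, 41 fell and 0 rose, with a median log2 fold change of -0.89; GINS4 fell from 1294 ± 34.4 to 298 ± 106, and the flap endonuclease gene FEN1 by 1.37 on the log2 scale. Of 41 mitotic genes, 39 fell and 0 rose (median -0.82), among them the mitotic kinase genes CDK1, from 958 ± 1.54 to 371 ± 106, and AURKA, whose log2 fold change was -1.07. Of 48 replication-dependent histone genes, 42 fell and 0 rose (median -0.94), including H2BC9 (log2 fold change -1.76) and H2AC11 (-1.02); histone genes have near-identical copies, so single members are uncertain. Adjusted over the list alone, 42, 39 and 42 members fell, respectively, and in all 3 lists 0 members were higher at an unadjusted p under 0.05 or by edgeR or DESeq2. The camera test called the 3 lists lower (adjusted p = 1.24e-13, 1.15e-11 and 1.24e-13), and each had an adjusted p = 0.695 with an estimated correlation.

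Of 39 DNA double-strand break repair genes, 21 fell and 4 rose, with 23 and 4 adjusted over the list alone and a median log2 fold change of -0.47. XRCC3 (-1.40) and the Fanconi anaemia gene FANCI (-1.13) fell, whereas the end-joining gene XRCC4 rose by 1.96 and TP53BP1 by 0.71. Of 78 ribosomal protein genes, 30 fell and 1 rose, with 28 and 1 adjusted over the list alone and a median of -0.23. RPL36 fell by 0.90 and RPL29 by 0.77, while RPL3 rose by 0.32. The call of RPL3 was lost with the libraries scaled to the same total (adjusted p = 0.0735), and without the first siCtrl library (log2 fold change 0.20, adjusted p = 0.292), either siSFPQ-2 library (0.0651 and 0.0553) or the second siSFPQ-3 library (0.0626). The camera test called both lists lower (adjusted p = 5.18e-03 and 1.40e-05), and each had an adjusted p = 0.781 with an estimated correlation. With siSFPQ-3 alone, 12 repair genes fell and 3 rose and the list was not called (camera adjusted p = 0.130), against 21 and 3 with siSFPQ-2 (adjusted p = 1.87e-04).

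Lists of mesenchymal, signalling and adherent-cell genes leaned upwards. Of 29 TGF-beta response genes, 18 rose and 5 fell (the same numbers adjusted over the list alone; median 0.62), with N-cadherin, CDH2, rising from 1161 ± 98.5 to 5462 ± 1457 and PMEPA1 by 3.05, while ID2 fell by 1.28 and SNAI2 by 0.95. Of 26 YAP and TEAD target genes, 16 rose and 2 fell (17 and 2 adjusted over the list alone; median 0.41); CRIM1 rose by 1.35 and AMOTL1 from 574 ± 9.76 to 1277 ± 170, while GGH fell by 1.06 and RBMS3 by 0.78, the latter with an adjusted p = 0.0538 without the first siCtrl library. Of 25 genes of the non-neuroendocrine state of small cell lung cancer, 16 rose and 5 fell (17 and 5 adjusted over the list alone; median 0.56). Annexin A1, ANXA1, rose by 4.61 in this list, whereas CCND1, the cyclin D1 gene, fell by 1.18 and MYC by 0.57. Of 36 immediate early genes, 18 rose and 4 fell (the same adjusted over the list alone; median 0.35), with the ERK phosphatase gene DUSP6 rising from 438 ± 69.9 to 4922 ± 1067 and KLF6 by 1.96, while DUSP2 fell by 0.94. Camera called these lists higher (adjusted p = 1.07e-03, 8.66e-04, 8.66e-04 and 0.0177), and each had an adjusted p = 0.695 with an estimated correlation.

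Markers of other cell types also moved. Of 7 tested epithelial genes, 4 rose and 1 fell, ELF3 by 2.89 and the keratin gene KRT18 by 3.24 upwards and CLDN7 by 0.80 downwards (median 1.40; 4 and 1 adjusted over the list alone); camera called the list higher (adjusted p = 0.0176), with an adjusted p = 0.695 with an estimated correlation. Of 8 fibroblast genes, 3 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.594), the collagen VI genes COL6A1 and COL6A2 rising by 1.43 and 1.29, with log2 fold changes of -0.53 for SPARC and -0.32 for COL5A1. The call of COL5A1 was lost without either siCtrl library (adjusted p = 0.0932 and 0.288), the second siSFPQ-2 library (0.0840) or the second siSFPQ-3 library (0.0863), at the same total (0.0533) and by DESeq2 (0.0585). Of 6 immune cell genes, 3 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.354), with ITGAX rising by 2.83 and CD79A from 13.2 ± 9.59 to 31.9 ± 7.36, while CD68 fell by 0.49. Without the first siCtrl library the adjusted p was 0.0786 for CLDN7, 0.0959 for CD68 and 0.243 for CD79A (log2 fold change 0.63, against 2.13 without the second), and without the second it was 0.0837 for CLDN7 and 0.0877 for CD68. Of 12 genes of the neuroendocrine state, 4 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.631); RTN1 rose by 1.23 and SYT11 by 0.68, and the Notch ligand gene DLL3 fell by 0.83, with an adjusted p = 0.0557 and 0.0744 without the first and the second siCtrl library. Of 30 p53 target genes, 15 rose and 4 fell (the same adjusted over the list alone; median 0.24), PMAIP1 by 2.35 and the death receptor gene TNFRSF10B by 1.11 upwards and DDB2 by 0.64 and TP53I3 by 0.40 downwards; the list was not called (camera adjusted p = 0.0551), but was called without the first siCtrl, siSFPQ-2 or siSFPQ-3 library (adjusted p = 0.0225, 0.0381 and 0.0335) and without a filter (0.0389). The call of TP53I3 was lost without the first siCtrl library (adjusted p = 0.0592). No list call in any comparison held with an estimated correlation. With both siRNAs, camera gave 1 of the 35 lists an unadjusted p under 0.05 in that setting. The correlation is then estimated from 6 libraries in 3 groups, which leaves little power. A call lost there therefore does not show that a list was unchanged. The estimates were 0.623 for E2F, 0.716 for mitotic, 0.628 for histone and 0.658 for ribosomal protein genes, against the preset 0.01. If they hold, the camera p-values of these lists at the preset correlation are too small. In the lists called higher the estimates lay between -0.023 and 0.122.

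**Figure D1:**
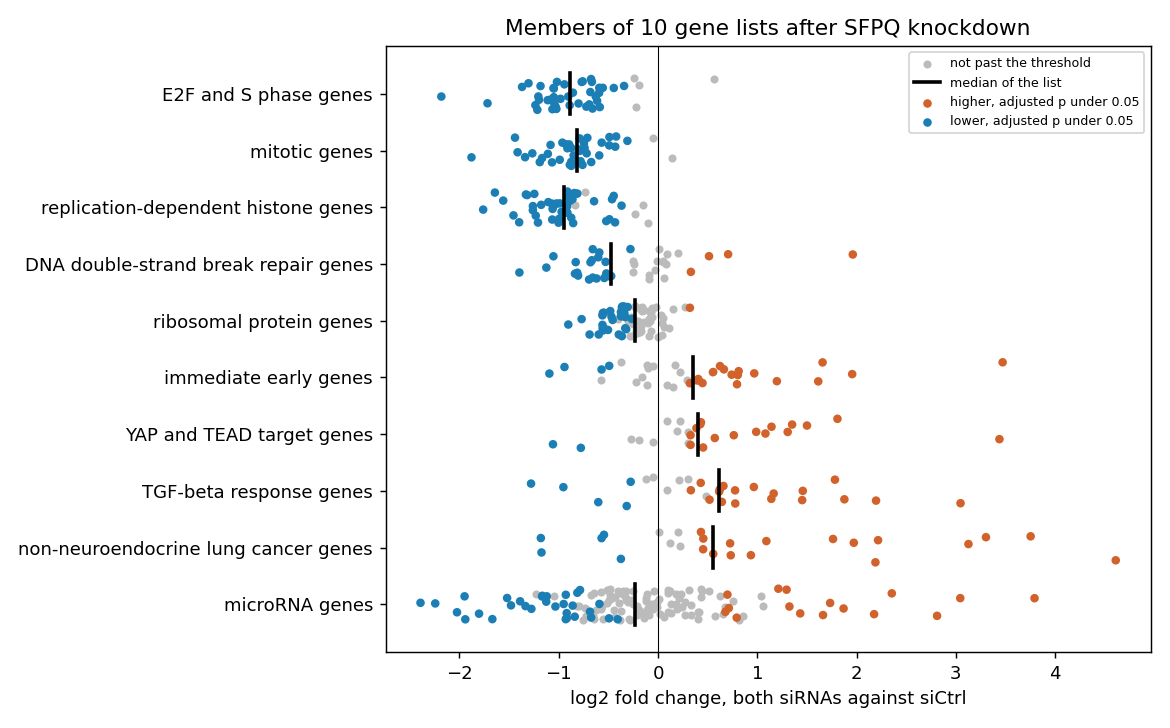
Each point is a gene of the list named at the left, at its log2 fold change for both siRNAs against siCtrl (n = 4 against n = 2 libraries); orange and blue points passed an adjusted p under 0.05 upwards and downwards, grey points did not, and vertical bars are list medians. The medians of the E2F, mitotic and histone lists lie at -0.89, -0.82 and -0.94, and the points of the microRNA gene list spread to both sides of its median of -0.23 (0.061 without a filter).

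Primary microRNA transcripts changed in both directions. Among 41 long non-coding hosts of microRNAs, 11 rose and 16 fell, the same numbers adjusted over the list alone. Of all tested long non-coding RNAs, 19.9% rose and 26.7% fell. MIR17HG, host of the miR-17-92 cluster (chromosome 13, 91347687 to 91354577), fell from 1625 ± 190 (SD, n = 2) to 854 ± 91.3 (SD, n = 4), a log2 fold change of -0.93 (SE 0.12, adjusted p = 1.08e-04), and MIR497HG fell by 1.55. C1orf61, MIR1915HG and MIR762HG fell by 0.89, 0.82 and 0.88. MIR181A1HG rose from 31.0 ± 3.21 to 364 ± 119, a log2 fold change of 3.45 (SE 0.15, adjusted p = 1.21e-07); MIR4500HG, MIR4435-2HG, CYTOR and LINC01138 rose by 1.93, 1.29, 1.20 and 0.89. The list as a whole was not called (camera adjusted p = 0.629).

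Among 52 protein-coding hosts, 17 rose and 10 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.443). Of all tested protein-coding genes, 28.4% rose and 23.0% fell. VMP1 (chromosome 17, 59707654 to 59842255) rose from 2083 ± 381 to 7387 ± 1460, a log2 fold change of 1.82 (SE 0.13, adjusted p = 1.90e-06), and PDE2A, CCPG1, LPP and SLIT2 rose by 2.37, 1.04, 1.05 and 0.81. IGF2, DNM3, SKA2, PPARGC1B and PANK1 fell by 1.79, 1.19, 0.99, 0.59 and 0.56, and the call of PPARGC1B was lost without the first siCtrl library (adjusted p = 0.0564). Over all 21773 tested genes, 5400 were higher and 5044 lower, so that 48.0% changed. Of 150 microRNA genes annotated as features of their own, 16 were higher and 31 lower, or 13 and 19 adjusted over the list alone. Their median was -0.23 (camera adjusted p = 0.162). The median was 0.061 without a filter and -0.39 with a filter at 50. Without a filter 38 were higher, and with a filter at 50, which tests fewer, 6 were higher and 17 lower. MIR21 rose from 9.94 ± 6.23 to 71.5 ± 20.2, but lies from 59841266 to 59841337 inside the end of the VMP1 span. Its reads therefore cannot be told from those of VMP1. Overlap of the other microRNA features with longer transcripts was not tested, so their reads may also belong to such transcripts. MIR378D2 rose by 1.87, and MIR3180-1, MIR3180-2 and MIR3180-5 by 2.18, 3.79 (5.88 and 2.07 at pseudocounts of 0.1 and 5) and 1.66; the MIR3180 features are near-identical copies and their values uncertain. MIR3185, MIR3175, MIR3143 and MIR4469 fell, with log2 fold changes of -2.24, -1.28, -1.94 and -0.93, as did MIR1-1HG-AS1 (-2.39), an antisense transcript that the naming rule let in; whether reads were counted by strand is not given in the sources used here, so its value is uncertain. Without the first siCtrl library 11 microRNA genes were lower, and without the second 8.

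Genes of paraspeckles and of microRNA processing changed in both directions, in smaller shares than the 48.0% that changed over all tested genes. Of 26 paraspeckle genes, 3 rose and 5 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.292); beside NEAT1, RBM7 rose by 0.51, and RBM14 fell by 0.57. Of 32 microRNA biogenesis and effector genes, 6 rose and 5 fell, the same adjusted over the list alone. The uridylyltransferase genes TUT4 and TUT7 rose by 0.61 and 0.74, whereas RAN fell by 0.46 and DGCR8, the partner of DROSHA in the Microprocessor, by 0.39, from 1291 ± 31.8 to 991 ± 80.8. The call of DGCR8 was lost without either siCtrl library (adjusted p = 0.0764 and 0.0524), that of RBM7 without the first (adjusted p = 0.0782) and that of RAN without the second (adjusted p = 0.0810). The median of the list was -0.03 and its mean 0.02, opposite in sign, with camera pointing down (adjusted p = 0.880).

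Each siRNA alone gave a similar count. With siSFPQ-2, 4621 genes were higher and 3906 lower, and with siSFPQ-3, 5007 and 4436. Of these, 4021 were higher with each siRNA, where independent lists would share 1063, and 3041 lower with each, where they would share 796; 4 genes were called in opposite directions. MIR17HG fell with each (log2 fold changes -0.85 and -1.01), NEAT1 rose with each (0.67 and 0.65), and so did TNFRSF9 (4.58 and 4.53). Of the mitotic genes, 38 fell with siSFPQ-2 and 20 with siSFPQ-3 (medians -1.19 and -0.48), of the E2F and S phase genes 42 and 30 (-1.05 and -0.60), and of the histone genes 41 and 38 (-1.02 and -0.85). Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.918 and Spearman's rho 0.898, against 0.496 and 0.452 in 20 simulations of unchanged groups sharing these controls. The covariance was 0.608 against 0.0345 simulated, a difference of 0.574. The 2 siCtrl libraries cannot be split into sets of 2, so part of the excess in shared calls may come from the shared controls. Without the first siCtrl library, 1792 genes were lower with siSFPQ-2 and 2082 with siSFPQ-3; without the second, 1849 and 2127, and 2914 were higher with siSFPQ-2. Without the second siSFPQ-2 library, 3029 were higher and 1984 lower with that siRNA.

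Compared directly, 17 genes were higher and 5 lower with siSFPQ-3 than with siSFPQ-2, and 1649 and 1070 were so at an unadjusted p under 0.05. ALPK2, which encodes an alpha-kinase, had 438 ± 22.7 normalized reads with siSFPQ-3 and 173 ± 7.58 with siSFPQ-2 (SD, n = 2 each), a log2 difference of 1.33 (SE 0.14, adjusted p = 0.0264). CKAP2L, ABLIM1 and the mitotic kinesin gene KIF2C were also higher with siSFPQ-3, by 1.22, 1.12 and 0.95, as was HKDC1, with 783 ± 175 against 351 ± 18.9. Of the 5 lower genes, SH3RF3 met the rule for named genes (log2 difference -0.70); the others, named after their values were seen, were HS3ST3B1 (-1.50), ACKR3 (-1.10), KLF2 (-1.63) and the long non-coding AC073071.1 (-1.67). In the lists, E2F and S phase genes had a median log2 difference of 0.45 and mitotic genes one of 0.68 (camera adjusted p = 1.17e-19 and 1.62e-28), with an adjusted p = 0.630 with an estimated correlation for each. Without the second siSFPQ-2 library these medians were 0.25 and 0.39, and without the first 0.68 and 0.99. Adjusted over the list alone, 30 and 35 of their members were higher with siSFPQ-3, against 0 and 1 over all genes tested; at an unadjusted p under 0.05 these were 32 and 35, edgeR called 0 and 2 and DESeq2 7 and 11. These gene counts were unstable, and edgeR on all libraries gave 40 higher and 11 lower and DESeq2 208 and 47. A replicate block gave 572 higher and 188 lower, and siSFPQ libraries of the same number deviated together with r = 0.382. With libraries scaled to the same total the balance turned. There 1001 genes were higher and 1661 lower at an unadjusted p under 0.05, and 1 and 0 at an adjusted p under 0.05. Without either siCtrl library or the second siSFPQ-2 library limma called 0 genes in either direction, with 1430, 1430 and 1112 higher and 779, 767 and 730 lower at an unadjusted p under 0.05. Without the first siSFPQ-2 library 213 were higher and 32 lower, without the first siSFPQ-3 library 90 and 95, and without the second 48 and 11.

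Nascent reads varied with gene span. Among 13576 protein-coding genes with a span in the RefSeq table, which is 96.8% of those tested, genes over 100 kb had a median log2 fold change of 0.31 with both siRNAs, 50.9% of them higher and 11.7% lower. Genes under 10 kb had a median of -0.19, 15.3% higher and 33.1% lower, and genes of 10 to 30 kb and 30 to 100 kb had medians of -0.08 and 0.10. Of the longest, genes of 100 to 300 kb had a median of 0.33 (52.6% higher and 10.5% lower), and it was 0.21 in genes over 300 kb (44.2% and 16.9%). With siSFPQ-2 these medians were 0.29 and 0.115, and with siSFPQ-3 0.37 and 0.25. CNTNAP2 and the kainate receptor gene GRIK2 (log2 fold change 2.57) were among the long genes that rose, and ROBO2 (-1.26) and EPHA7 (-0.63) among those that fell. Spearman's rho between span and fold change across genes, which are not independent replicates, was 0.291 with both siRNAs, 0.241 with siSFPQ-2 and 0.329 with siSFPQ-3. It was 0.272 for siSFPQ-3 against siSFPQ-2, groups given siRNAs against the same target. The median over genes above 100 kb minus that of genes under 10 kb, each against the siCtrl mean, was 0.08 and -0.08 in the siCtrl libraries, 0.39 and 0.43 with siSFPQ-2, and 0.71 and 0.50 with siSFPQ-3. The smallest distance between an siSFPQ and a siCtrl library was 0.31, against a largest distance of 0.21 within a group and of 0.32 between an siSFPQ-2 and an siSFPQ-3 library. A fixed list of 45 long neuronal and adhesion genes held 17 that rose and 9 that fell (17 and 10 adjusted over the list alone); its median was -0.05 and its mean 0.26, of opposite sign, with camera pointing up (adjusted p = 0.300). Its median was 0.15 without the second siCtrl library and 0.036 and 0.048 without the first and the second siSFPQ-3 library. Over all tested genes 76.6% had a span, too few for the check to count.

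**Figure D2:**
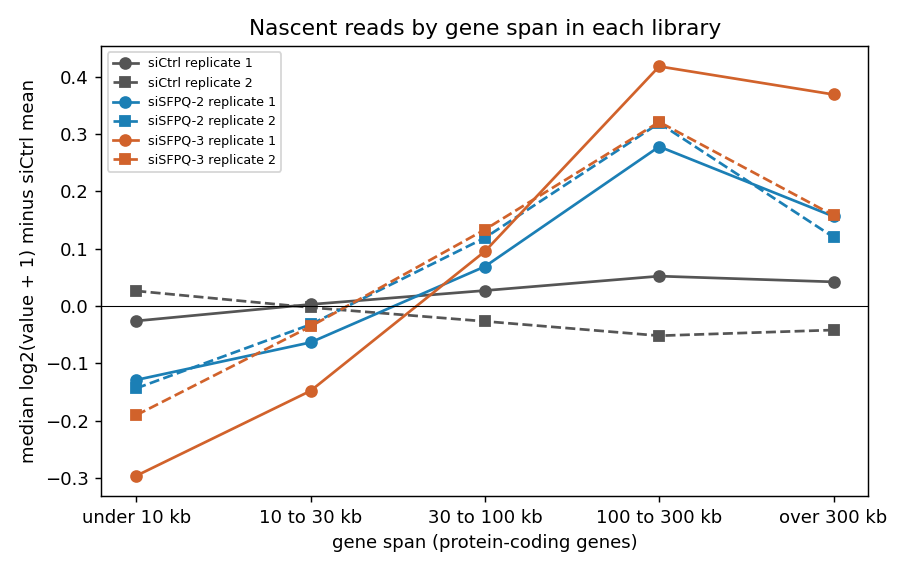
Lines give, for each of the 6 libraries, the median over protein-coding genes in 5 classes of gene span (horizontal axis) of log2(value + 1) minus the mean of the siCtrl libraries (vertical axis); the siCtrl lines mirror each other because they are set against their own mean. Under 10 kb the 4 siSFPQ libraries lie between -0.13 and -0.30, and between 100 and 300 kb they lie above both siCtrl libraries.

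The position of the signal along genes was followed in the authors' deposited profiles, which divide genes into classes named up, ns and down. In the class up, promoter signal near the start site went from 355 ± 7.30 per bin (SD, n = 2) in siCtrl to 475 ± 65.6 (SD, n = 4) in the siSFPQ libraries, a log2 ratio of 0.42, and the signal downstream from 36.0 ± 2.70 to 71.3 ± 1.02, a log2 ratio of 0.99. The promoter ratio was 0.91 as a median over genes. With each gene scaled to its own total, which measures shares within genes, it reversed to -0.30 and the downstream ratio was 0.13. In the class down, the corresponding log2 ratios were -0.65 (755 ± 19.4 to 481 ± 37.3) and -0.86 (97.8 ± 4.28 to 53.7 ± 6.09), or -0.021 and -0.066 with each gene scaled to its own total. Class ns had 329 ± 8.90 and 285 ± 37.8 at the promoter and 25.2 ± 0.876 and 24.1 ± 0.705 downstream. Its downstream log2 ratio of -0.069 turned to 0.12 as a median over genes and to 0.0056 with each gene scaled to its own total. Because 2 against 4 libraries make 15 splits, the smallest one-sided p of an exact permutation test is 0.0667, so no call was possible; the up and down classes reached that value and ns gave 0.133 in each window. The classes were chosen by the authors on these libraries, so their directions are not independent evidence.

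Gene by gene, limma called 502 genes with higher and 625 with lower promoter signal among 20515, and 5022 with higher and 3766 with lower signal downstream. The promoter counts fell to 0 in both directions when any library was omitted, with 3369 to 6360 genes at an unadjusted p under 0.05; requiring signal in at least 3 libraries, a choice made after seeing the data, gave 753 and 1041, and between 70 and 559 higher and between 7 and 1217 lower as each library was omitted in turn. Downstream, 3085 genes were higher and 1613 lower without the first siCtrl library, and 2984 and 959 without the second.

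**Figure D3:**
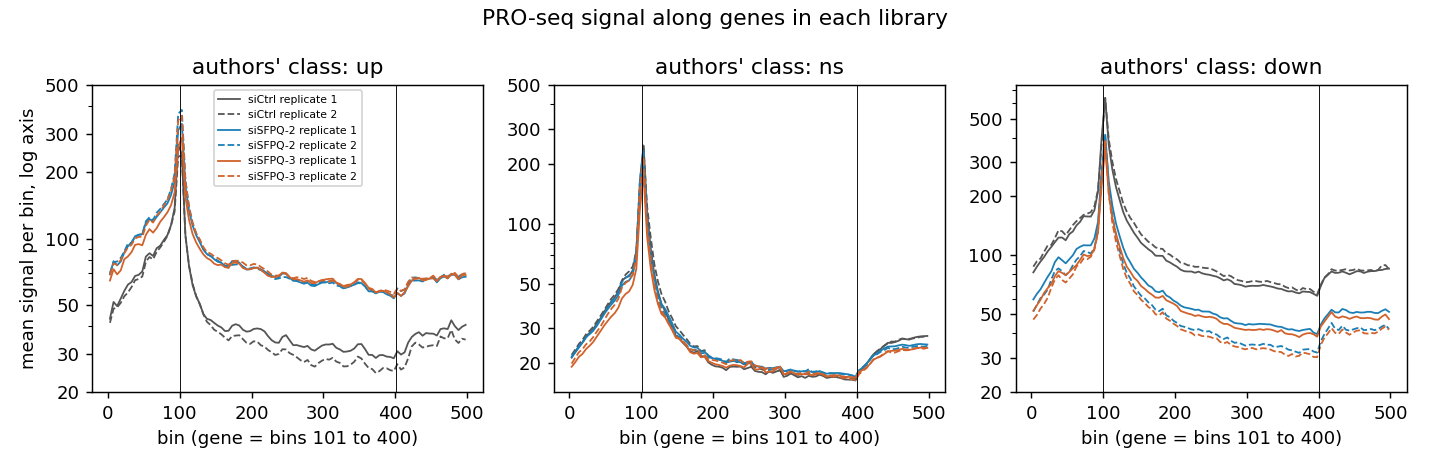
Mean signal per bin (vertical log axis) along 500 bins (horizontal axis; the gene, scaled to one length, is taken to fill the middle 300 bins) for the authors' classes up, ns and down, with 1 line per library smoothed over 5 bins and a separate vertical range in each panel. In the class up the siSFPQ lines lie above the siCtrl lines downstream of the start site (71.3 against 36.0 per bin on average), and in the class down below them (53.7 against 97.8).

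The class files listed 3402 genes as up, 46081 as ns and 2528 as down. Of 3300 tested genes of the class up, 3294 were called higher, with a median log2 fold change of 1.09 (SD 0.78 across genes), and of 2463 of the class down, 2457 were called lower, with a median of -0.90 (SD 0.42). No gene of either class had a fold change of the opposite sign. Of 14896 tested genes of the class ns, 1949 were called higher and 2394 lower. The classes up and down follow the fold as well as the adjusted p. In all, 3264 and 2430 of these genes but 4 of class ns had an adjusted p under 0.05 and a change over 1.5-fold in the authors' deposited table. SFPQ, NONO and PSPC1 were in the class ns, NEAT1 in up and MIR17HG in down. The authors' deposited table gave log2 fold changes of 0.67 for NEAT1 (adjusted p = 2.41e-06), -0.93 for MIR17HG (adjusted p = 1.53e-09) and -0.21 for SFPQ (adjusted p = 0.252). At an adjusted p under 0.05, the authors' deposited table held 4731 features higher and 4027 lower.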

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

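The test of the fall of proliferation genes with each siRNA alone, and the tests of lists between the siRNAs without single libraries, were chosen after the result was seen.

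Differences between the siRNAs were tested directly, as siSFPQ-3 against siSFPQ-2, and gave 17 genes higher and 5 lower with siSFPQ-3; limma called 0 without either siCtrl library or the second siSFPQ-2 library (1430, 1430 and 1112 higher and 779, 767 and 730 lower at an unadjusted p under 0.05; edgeR and DESeq2 on all libraries gave 40 and 208 higher and 11 and 47 lower). Without the first siSFPQ-2 library the counts were 213 and 32, without the first siSFPQ-3 library 90 and 95, and without the second 48 and 11. A replicate block on all libraries gave 572 higher and 188 lower, and siSFPQ libraries of the same number deviated together with r = 0.382. Camera at the preset correlation also found 10 gene lists that differed between the siRNAs. Mitotic genes had a median log2 difference of 0.68 (adjusted p = 1.62e-28), E2F and S phase genes 0.45 (adjusted p = 1.17e-19), spliceosomal and 7SK small nuclear RNA genes 0.24 (adjusted p = 2.12e-03), YAP and TEAD target genes 0.23 (adjusted p = 9.09e-05), and DNA double-strand break repair genes 0.21 (adjusted p = 2.07e-07). SR and hnRNP splicing factor genes had a median log2 difference of 0.097 (adjusted p = 0.0321) and non-neuroendocrine lung cancer genes one of 0.085 (adjusted p = 0.0475). Lower with siSFPQ-3 were unfolded protein response genes (median -0.14, adjusted p = 9.09e-05), oxidative phosphorylation genes (-0.074, adjusted p = 0.0181) and integrated stress response genes (-0.069, adjusted p = 0.0321). The adjusted p of these 10 lists lay between 0.577 and 0.898 with an estimated correlation. Single libraries ended 5 of these calls. Without the first siSFPQ-2 library the adjusted p was 0.392 for non-neuroendocrine, 0.126 for integrated stress response and 0.224 for splicing factor genes. Without the second it was 0.602 for oxidative phosphorylation and 0.130 for small nuclear RNA genes. Without the first siSFPQ-3 library it was 0.106 for integrated stress response and 0.534 for oxidative phosphorylation genes, and the median of the small nuclear RNA genes turned to -0.026 (adjusted p = 0.796). Without the second it was 0.371 for non-neuroendocrine and 0.761 for splicing factor genes. Among lists that kept a call, the medians without the second siSFPQ-2 library were 0.39 for mitotic and 0.25 for E2F genes, and without the first 0.68 for E2F genes; that of unfolded protein response genes was -0.084 without the first siSFPQ-3 library.

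The E2F, mitotic and histone genes, 134 in all, fell with a median log2 fold change of -0.89. TMM and same-total scaling do not account for this, since the higher of the medians after them was -0.90. They moved the median of all genes only from -0.019 to -0.034 and -0.057, so they could hardly have changed it. A scaling to fly reads, which could shift all genes alike, could not be tried. Gene span and expression level do not account for the fall, since the lowest of 10000 random lists matched on both had a median of -0.29. An effect of 1 siRNA alone is argued against for E2F genes, narrowly, since the median of each siSFPQ library lay at least 0.55 below that of each siCtrl library, against a largest distance of 0.50 within a group and a median difference of 0.45 between the siRNAs (0.68 without the first siSFPQ-2 library). For mitotic genes (0.31 against 0.62) and histone genes (0.57 against 0.60) it cannot be told apart from an effect of both, because libraries of 1 group differ by more, and the mitotic difference between the siRNAs (0.68) exceeds the median of -0.48 with siSFPQ-3 in size. An off-target or toxic effect common to both siRNAs was not tested. No list kept its call with an estimated correlation, a setting of little power with so few libraries. The estimates for these lists were 0.623, 0.716 and 0.628, against the preset 0.01, so their p-values at the preset correlation may be too small. The pattern is not called biological.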

How the results depend on the processing

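The alternative of gene body bins alone and that of windows with signal in at least 3 libraries were chosen after seeing the data. Under single alternatives, 3842 of the values that could be compared stayed the same. They kept their direction and their side of the threshold, or stayed within the replicate spread or 1.5 times the count. Another 67 were no longer past the threshold, 19 came past it and 96 moved. Moved values lay further off, or changed direction with no adjusted p under 0.05 in either setting. The 3 counted as reversed, all ratios of profile signal, also changed sign. For named genes the numbers were 2939, 41, 2, 1 moved and 0 reversed. The 1 moved was ALPK2, which changed sign to 0.019 without the first siCtrl library. All 8 moved values of gene lists were such changes of direction. The count of genes with both siRNAs was 4716 higher and 4084 lower by DESeq2 and 5521 and 5010 by edgeR. No scaling moved the median of all genes by 0.1 or more, nor the share of higher calls by over 10 points (51.7% as deposited, 49.9% after TMM and 48.8% at the same total). Where a cause is not named below, the cause was not tested. Fits that leave out a library leave 1 sample in its group, which is assumed to vary like the other groups.

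Requiring a fold of at least 1.5 left by construction 2879 lower genes with both siRNAs, 2600 with siSFPQ-2 and 2797 with siSFPQ-3. With each library left out, lower genes ranged from 2463 to 5205 with both, from 1792 to 4414 with siSFPQ-2 and from 2082 to 4571 with siSFPQ-3, and higher genes with siSFPQ-2 from 2914 to 4904; the lowest values came without a siCtrl library. Of genes higher and lower with siSFPQ-3 than with siSFPQ-2, limma called 5 and 0 at a pseudocount of 0.1, 3 and 0 at a filter of 50, 3 and 0 after TMM, 1 and 0 at the same total, and 39 and 11 with robust empirical Bayes. At an unadjusted p under 0.05 the lower genes behind these 0 counts were 1073, 951, 1296 and 1661. The higher genes were then 1626, 1450, 1474 and 1001, so the balance turned at the same total. edgeR called 40 and 11 and DESeq2 208 and 47, and leaving out libraries gave 0 to 213 and 0 to 95. Samples of the same replicate number deviated together with r = 0.382 between the siSFPQ groups, and with 0.0529 and 0.0587 between these and siCtrl. The numbers were therefore not taken to pair the samples of all 3 groups. Outside its own group, each siSFPQ library was closest to that of the same number with the other siRNA. A pairing of the siSFPQ groups stays open, and with it the counts between the siRNAs. With a replicate block, 6027 genes were higher and 5906 lower with both siRNAs, 572 higher and 188 lower between the siRNAs, SFPQ, at -0.22, had an adjusted p = 0.0492, and the p53 target list one of 0.0433. Without single libraries SFPQ ranged from -0.31 (adjusted p = 0.0255) to -0.13 (adjusted p = 0.322).

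With an estimated correlation camera called 0 lists higher and 0 lower, against 5 and 7 at the preset one, and fry called 8 and 3, with an adjusted p of 0.0531 for mitotic, 0.0502 for histone, 0.0758 for repair, 0.107 for ribosomal protein and snoRNA host and 0.265 for small nuclear RNA genes. Lists that fry called and camera did not were interferon-stimulated (0.00611), Notch target (0.0140), fibroblast (0.0470), clock (0.0482) and p53 target genes (0.0486). Without a filter 38 microRNA genes were higher; with a filter at 50, which tests fewer, 6 were higher and 17 lower, and leaving out libraries gave 8 to 33 lower. Spearman's rho with span over all matched genes was 0.182 without a filter and 0.301 with a filter at 50. Pearson's r between the siRNAs was 0.874 without a filter and 0.945 in genes above the median by mean, where 2449 genes were higher and 1727 lower with each.

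In the class up, the log2 ratio of promoter signal was 0.91 as a median over genes and -0.30 with each gene scaled to its own total, which measures shares within genes. Downstream it was 1.35, 0.13, 1.05 at the same total and 1.01 in gene body bins, and ranged from 0.91 to 1.07 without single libraries. In the class ns, downstream, it was 0.12 as a median, 0.0056 scaled to own totals and -0.00074 at the same total. In the class down it was -0.84 at the promoter as a median, -0.021 scaled to own totals, and -0.066 downstream scaled to own totals. A promoter window of 300 bases gave 845 higher and 1375 lower genes, and windows with signal in at least 3 libraries gave 1041 lower. With a replicate block, or with any 1 library left out, limma called 0 and 0, while between 3369 and 6360 genes had an unadjusted p under 0.05. In these fits at least 89 windows have no variance, and the prior degrees of freedom with all libraries were 2.03. Requiring signal in at least 3 libraries, which leaves 19990 of 20515 windows, gave 3.92, and 662 and 865 genes with the replicate block; leaving out only the windows without variance was not tried. Downstream, leaving out libraries gave 2984 to 4552 higher and 959 to 3778 lower.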

Other observations

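Chosen after the result was seen were the tests on gene bins 301 to 400, on each siRNA's correlation with span and on genes of 30 to 100 kb. The ratios between windows and the split of genes at 300 kb were not planned before the data were examined.

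With both siRNAs against siCtrl, further gene lists, that of Notch targets excepted, held genes that rose and genes that fell. Over all tested genes 48.0% changed. Of 34 interferon-stimulated genes, 14 rose and 6 fell (15 and 7 adjusted over the list alone; camera adjusted p = 0.300), with DDX58, the gene of the RNA sensor RIG-I, rising by 1.21 and IFITM1 by 1.47, while IFI44L fell by 1.05 beside IFIT1. Of 31 integrated stress response genes, 7 rose and 11 fell (8 and 12 adjusted over the list alone; adjusted p = 0.300), the cystine transporter gene SLC7A11 rising from 212 ± 55.3 (SD, n = 2) to 1349 ± 63.9 (SD, n = 4) and WARS1 by 0.92, while PSAT1 fell by 1.26 and DDIT4 by 1.00. Of 32 unfolded protein response genes, 8 rose and 9 fell (adjusted p = 0.599), EDEM1 rising by 1.26 and SEC24D by 0.90, whereas SDF2L1 fell by 1.21 and CRELD2 by 0.75. Of 29 cholesterol synthesis genes, 12 rose and 6 fell (adjusted p = 0.314), FDFT1 rising by 0.91 and DHCR7 by 0.82, whereas PMVK fell by 1.13 and HSD17B7 by 0.86. Of 38 hypoxia and glycolysis genes, 12 rose and 9 fell (12 and 11 adjusted over the list alone), the glucose transporter gene SLC2A3 rising from 14.1 ± 2.65 to 225 ± 77.1 and BHLHE40 by 1.89, while HK2 fell by 1.07 and TPI1 by 0.86; the median was -0.05, the mean 0.15 and camera pointed up (adjusted p = 0.989). This median was 0.057 without the first siCtrl and 0.0015 without the first siSFPQ-3 library. Of 24 heat shock genes, 5 rose and 5 fell, BAG3 rising by 0.85 and DNAJB6 by 0.73, whereas HSPA8 fell by 0.68 and FKBP4 by 0.63; the median was -0.06, the mean 0.04 and camera pointed down (adjusted p = 0.724), and the median turned to 0.03 without the second siCtrl library. Of 15 Notch target genes 7 fell, HES6 by 0.52 beside CCND1, and limma called 0 higher, as did edgeR and DESeq2, with 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.137). Of 20 circadian clock genes, 5 rose and 7 fell (adjusted p = 0.658), CRY1 rising by 0.94, whereas NR1D1 fell by 1.26 and DBP by 0.92. For the unfolded protein response, cholesterol, heat shock, Notch and clock lists, the numbers adjusted over the list alone were the same.

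Lists of transcription, RNA processing and oxidative phosphorylation genes likewise held members that rose and members that fell. Of 38 RNA polymerase II pausing and elongation genes, 14 rose and 6 fell (the same adjusted over the list alone; camera adjusted p = 0.300), ELL2 rising by 1.27 and AFF1 by 0.87, whereas SSRP1 fell by 0.92 and MEPCE by 0.66. Of 45 SR and hnRNP splicing factor genes, 3 rose and 14 fell (2 and 14 adjusted over the list alone; adjusted p = 0.0575), PTBP3 rising by 1.15 and SF3B1 by 0.31, whereas PTBP1 fell by 0.59 and HNRNPUL2 by 0.57. This list was called lower without the first siCtrl library (adjusted p = 0.0247) and the second siSFPQ-3 library (0.0172), without a filter (0.0438), at the same total (0.0351) and with siSFPQ-2 alone (0.0126). Of 38 cleavage, polyadenylation and Integrator genes, 5 rose and 5 fell (3 and 3 adjusted over the list alone; adjusted p = 0.631), XRN2 rising by 0.62 and PAPOLG by 0.61, whereas CPSF1 fell by 0.60 and CPSF4 by 0.42. Of 16 SIN3A and histone deacetylase genes, 3 rose and 2 fell (the same adjusted over the list alone; adjusted p = 0.354), HDAC1 rising by 0.69 and ARID4B by 0.55, whereas SAP30 fell by 0.48 and RBBP7 by 0.39. Of 55 oxidative phosphorylation genes, 3 rose and 13 fell (2 and 9 adjusted over the list alone; adjusted p = 0.1002), COX6C rising by 0.49 and COX7A2 by 0.54, whereas CYC1 fell by 0.70 and NDUFB10 by 0.69. This list was called lower without the first siCtrl library (adjusted p = 0.0495), the second siSFPQ-2 library (0.0424) or the second siSFPQ-3 library (0.0464), and with siSFPQ-3 alone (0.0425). Of 26 snoRNA host genes, 1 rose and 9 fell (1 and 8 adjusted over the list alone; adjusted p = 0.0317, and 0.781 with an estimated correlation), SNHG16 rising by 0.49, whereas SNHG7 fell by 1.09 and SNHG10 by 0.74. Of 20 spliceosomal and 7SK small nuclear RNA genes, 1 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.0239, and 0.781 with an estimated correlation), RN7SK rising by 1.15, whereas RNU5D-1 fell by 1.48 and RNU4ATAC by 0.64; these genes have many near-identical copies and are uncertain.

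Omitting single siCtrl libraries ended some of these calls. Without the first, the adjusted p was 0.0732 for COX7A2, 0.0642 for SF3B1, 0.0636 for CPSF4, 0.130 for SNHG16, 0.0512 for RNU5D-1, 0.0665 for SAP30 and 0.0588 for RBBP7. Without the second, it was 0.173 for SF3B1, 0.0501 for PAPOLG, 0.0556 for CPSF4, 0.129 for RN7SK (log2 fold change 0.57, against 1.73 without the first), 0.0613 for ARID4B, 0.0592 for SAP30 and 0.0842 for RBBP7, and SF3B1 had 0.0564 without the second siSFPQ-2 library. The snoRNA host list was no longer called without the second siCtrl library (adjusted p = 0.0508) or the first siSFPQ-2 or siSFPQ-3 library (0.109 and 0.1996), by edgeR (0.0547) or with siSFPQ-3 alone (0.0501). The small nuclear RNA list was not called without the first siCtrl or second siSFPQ-3 library (0.0933 and 0.0976), without a filter (0.0912), by edgeR (0.0626) or with siSFPQ-3 alone (0.189).

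The ratio of promoter to body signal was lower with both siRNAs in genes of 30 to 100 kb, where its median log2 value went from 4.24 to 3.78 and limma called 35 genes higher and 644 lower of 3998. Camera called these genes lower (adjusted p = 1.18e-05), but not with an estimated correlation (unadjusted p = 0.327). Camera compares a set of genes with the other genes. Its smallest p was for genes under 10 kb, called higher relative to the others (adjusted p = 3.97e-11, and an unadjusted p = 0.306 with an estimated correlation). Their own median change was -0.035. In genes of 100 to 300 kb the medians were 3.61 and 3.04, with 17 genes higher and 363 lower of 1762 (camera adjusted p = 2.19e-05, and an unadjusted p = 0.409 with an estimated correlation), and in genes over 300 kb 2.81 and 2.59, with 9 and 41 of 359. In genes of 10 to 30 kb they were 4.09 and 3.84, with 42 and 252 of 3677, and in genes under 10 kb 2.93 and 2.89, with 43 and 81 of 2753. In the authors' classes, which were chosen on these libraries, the median change of the ratio was -0.62 in up (64 genes higher and 654 lower of 2106), -0.29 in ns (53 and 713 of 9116) and 0.073 in down (29 and 14 of 1327). The ratio of signal past the gene end to that in the 3' part of the body (bins 301 to 400) was lower in the siSFPQ median at each span, by 0.28 in genes over 300 kb (median change -0.28), where limma called 0 of 359 genes in either direction and 91 had an unadjusted p under 0.05.

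Long genes were higher and short genes lower with both siRNAs, with a Spearman's rho of 0.29 across protein-coding genes, though the median was 0.33 at 100 to 300 kb and 0.21 over 300 kb. Genes of few reads do not account for it, with a rho of 0.351 in the upper of 3 equal classes by mean value and 0.174 in the lowest. Without the E2F, mitotic, histone and ribosomal protein genes (211 genes) rho was 0.282. So few of 13576 genes could hardly have moved it further. That test therefore cannot decide whether a wider set of short genes that fell with these lists makes the trend. Knockdown of SFPQ would give the trend with each siRNA, and rho was 0.241 with siSFPQ-2 and 0.329 with siSFPQ-3. Both share the siCtrl libraries, however, and rho was 0.272 between the siRNAs themselves, so that knockdown cannot be told apart from other effects of the siRNAs or differences between these libraries. A fall of promoter-proximal reads, which weigh more in short genes, stays open too (rho 0.153 in bins 301 to 400, between the bounds set for that test, against 0.272 in all body bins, and a median log2 fold change of -0.18 of promoter signal over genes), as does the part of each gene that was counted, and the pattern is not called biological.

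In genes over 300 kb the 3' part of the body lost signal against the 5' part (bins 104 to 200), with medians of the log2 ratio of -0.24 and -0.27 in the siCtrl libraries, -0.46 and -0.53 with siSFPQ-2, and -0.47 and -0.61 with siSFPQ-3; among 359 genes the ratio fell in 61, such as TMTC2 (-2.15), GRIK2 (-2.02) and CUX1 (-2.09), and rose in 5, such as NFIA (2.03), all named after their values were seen. Camera called these genes lower (adjusted p = 1.20e-11), but not with an estimated correlation (unadjusted p = 0.102). A loss of 3' signal at all spans would lower the ratio in genes of 30 to 100 kb, where the median change was 0.097. The library medians there were -0.53 and -0.70 in siCtrl, -0.56 and -0.55 with siSFPQ-2, and -0.45 and -0.53 with siSFPQ-3. The siCtrl libraries differed by more than this change, so these genes cannot decide whether the loss is at all spans. How degraded RNA would act on PRO-seq signal was not tested. In genes under 10 kb the median change was 0.27, and the ratio rose in 321 genes and fell in 26 of 2753. Bins 104 to 200 lie nearer the start site in such short genes. A fall of promoter-proximal reads could raise the ratio there, so these genes do not decide the question. Low coverage stays open and may account for part of the change. The median was -0.082 (SE 0.030) in the 180 genes above the median by body signal, against -0.16 in all. Changes of isoform cannot be told apart from low coverage. The median of -0.15 (SE 0.035, 178 genes) in the class ns lies too near the bound set for that test. Both SEs come from resampling genes, which are not independent replicates, and leave out the spread between libraries. The pattern is not called biological.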
